A study of Homo sapiens with 5 samples.

How the data were processed

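Chromatin immunoprecipitation was sequenced in 1 library each for PRDM11 antibody 1, PRDM11 antibody 2 and RNA polymerase II in U2932 cells, with 1 rabbit IgG and 1 input library as controls. Cells were cross-linked and sonicated before precipitation, per the labels' protocols. The submitters' processing notes name Bowtie 0.12.7, SAMtools, MACS2 2.0.9 and the human build hg19, without giving their order or settings; by their usual roles these are a read aligner, a tool for alignment files and a peak caller. The deposited peak lists are 1 per ChIP library and control (6 in all), and only their names give the control and a q threshold of 0.1. Whether duplicate reads were removed is not given in the sources used here. Each list has 3 columns, the chromosome, start and end of a peak, and no score, fold or p-value. No peaks within a list overlap each other. Starts were counted from 0 and are printed here counted from 1.

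Samples were grouped by the antibody in their labels. Because the lists hold no read counts or coverage, depth is unknown and no precision could be derived from it. The single library per antibody allows no test between conditions, so shares are given with exact (Clopper-Pearson) 95% binomial intervals, which treat peaks as independent and cover counting error only. A peak counted as overlapping when it shared at least 1 bp with a peak of the other list. Chance overlap was estimated in 2 ways: by placing the peaks of the first list at random within the same chromosome (100 shuffles for lists called against IgG, 10 for lists called against input), between the first and last position any of the 6 lists reaches, and by moving all peaks by 50 kb in each direction. The shuffles do not exclude assembly gaps and so understate chance. A peak list called with a low threshold, a minimum width set by the fragment length, or a control that lacks reads in a region changes both the number of peaks and their overlaps.

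Before the data were examined, the IgG lists, the 1 bp overlap and the shuffle were fixed as the main settings. Alternatives fixed then were the lists called against input, different controls for the lists compared, chromosomes 1 to 22 and X, coverage of at least 50% of the peak, both controls, and the move of 50 kb. Also planned were a stricter threshold and lists of equal length ranked by score, the share of peaks at promoters within 1 kb of a start site, the genes with a shared region there, shares of fixed gene lists and the rank correlation of scores. The design assumed a score per peak and, for genes, an annotation of build hg19. None of these was run: the lists carry no scores, and no gene annotation of build hg19 was used here. The rule for named items therefore fell back to regions: the 10 shared regions and the 5 RNA polymerase II peaks that rank first, ranked by width in place of the score. Because antibody 1 and antibody 2 share the IgG control, part of their overlap may come from it; without reads this share could not be simulated, and lists with different controls were compared instead. Added after seeing the data were width classes, classes of peaks by overlap with both other lists, moves over other distances, distances to RNA polymerase II (the test at 5 kb was set before its own result was seen), positions within its peaks, densities per chromosome, runs of sparse bins, comparisons with both lists limited to peaks of 200 bp or more, the blocks of closely spaced peaks in the input lists, lists outside those blocks, and shuffles outside stretches of at least 200 kb without any peak (160 stretches, 193.9 Mb). Blocks were runs of 1-Mb bins with at least 50 antibody 1 peaks against input and at least 5 times the count against IgG plus 1; limits of 25 peaks and 3 times, and of 100 peaks and 5 times, were also tried.

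Overlaps were computed with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9. The procedure was tested on simulated data: 13499 simulated antibody 1 peaks, some planted on simulated antibody 2 peaks. It found 100% of the planted overlaps; unplanted peaks overlapped at 6.63% against 6.43% in shuffles. The count of 5960 overlapping peaks was identical to that of bedtools 2.31.1, and 4 of 4 planted blocks of 1 Mb were found with 0 others. Planted peaks were centred on the peaks they were to overlap, and unplanted peaks were placed by the same shuffle, so this checks the code only. The planted blocks were far denser than the limit for a block, so blocks near that limit were not tested.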

Results

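The series profiled chromatin of U2932 cells, an established human lymphoma cell line grown without treatment, by chromatin immunoprecipitation and sequencing (ChIP-seq). Chromatin was precipitated with antibody 1 or antibody 2, rabbit polyclonal antibodies raised against PRDM11, a member of the PR domain protein family, or with an antibody against RNA polymerase II, the enzyme that transcribes protein-coding genes. A rabbit IgG precipitate and an unprecipitated input library served as controls. Each of the 5 libraries was the only one of its kind, so no value below has an error between replicates and no p-value is given. Intervals are exact 95% binomial intervals over peaks and cover counting error only. By the names of the deposited lists, peaks were called per ChIP library, once against IgG and once against input, which gave 6 lists of intervals on the human build hg19. The lists hold positions without read counts, so the sequencing depth behind each peak is unknown, and peaks were not assigned to genes. Values refer to the lists called against IgG unless input is named.

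The 3 antibodies gave peak landscapes of very different size. Antibody 1 had 13499 peaks covering 3.56 Mb, RNA polymerase II had 50161 peaks covering 17.9 Mb, and antibody 2 had 465837 peaks covering 64.8 Mb. Antibody 2 peaks were mostly of the shortest length in the list: 78.4% were exactly 123 bp wide, against 20.4% of antibody 1 peaks at the same 123 bp minimum and 6.76% of RNA polymerase II peaks at their own minimum of 129 bp. Peaks of 500 bp or wider numbered 1441 for antibody 1, 691 for antibody 2 and 9465 for RNA polymerase II. The widest RNA polymerase II peak reached 13809 bp, while the widest peaks of antibody 1 and antibody 2 were 2136 bp and 1976 bp.

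In the lists called against IgG, antibody 1 and RNA polymerase II peaks were distributed alike over the chromosomes, and antibody 2 peaks more evenly. Chromosome 19, known for its high gene density, had the densest peaks of each library: 14.9 per Mb for antibody 1, 63.2 per Mb for RNA polymerase II and 229.6 per Mb for antibody 2. Chromosome X had the sparsest antibody 1 peaks (1.63 per Mb) and antibody 2 peaks (81.8 per Mb), so that the densest and sparsest chromosomes differed 9.13-fold for antibody 1 but 2.81-fold for antibody 2. Over 23 chromosomes, peak density of antibody 1 followed that of RNA polymerase II with Pearson's r = 0.98 and Spearman's rho = 0.97, and r was 0.95 without chromosomes 19 and 22, the pair farthest from the median. For antibody 2 the same values were r = 0.81, rho = 0.84 and, without chromosomes 19 and 22, r = 0.72. In the lists called against input the order was the opposite: r was 0.89 and rho 0.80 for antibody 1, with r = 0.64 without chromosomes 18 and 19, and r was 0.91 and rho 0.85 for antibody 2, with r = 0.84 without them. Chromosomes 18 and 3 held 25.2% and 21.4% of the antibody 1 peaks called against input, and the reduced values still include chromosome 3. How far these 2 chromosomes set the order was not tested. All these correlations are relations across chromosomes of single libraries, 3 of which were computed per control, and chromosomes are not independent replicates.

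The use of 2 antibodies against 1 protein asks which sites both recognise. Of the 13499 antibody 1 peaks, 6375 overlapped an antibody 2 peak by at least 1 bp, a share of 47.2% (46.4% to 48.1%); these 6375 are called shared PRDM11 regions here. Antibody 1 peaks placed at random within their chromosome overlapped antibody 2 peaks at 6.47% on average, with a range of 6.05% to 7.03% over 100 shuffles. After a move of 50 kb in either direction, which keeps peak density only on a broad scale, the share was 8.31%. The observed share was 5.68 times as high. Shorter moves of 5000 bp and 10000 bp gave 9.13% and 8.86%. In the reverse direction, 7423 of the 465837 antibody 2 peaks (1.59%) overlapped an antibody 1 peak, against 0.246% after a move of 50 kb. Both lists were called against the same IgG library, which can raise their overlap; with antibody 1 called against IgG and antibody 2 against input, 48.2% of antibody 1 peaks overlapped, against 8.83% after the move. When both lists were those called against input, 34.8% overlapped, 1.71 times the share after the move, and the number of shared regions was 18799. Outside the blocks of closely spaced input-list peaks (described below) the number was 8502.

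Wide peaks were shared far more often than narrow ones. Of the 2753 antibody 1 peaks of 123 bp, 16.1% (14.7% to 17.5%) overlapped an antibody 2 peak, against 5.21% after a move of 50 kb. The share was 55.4% for the 2648 peaks of 200 to 299 bp and 96.2% (95.03% to 97.2%) for the 1249 peaks of 500 to 999 bp, where the share after the move was 15.6%. All 192 antibody 1 peaks of 1000 bp or wider overlapped an antibody 2 peak. Antibody 2 peaks followed the same course more steeply: 0.693% of the 365239 peaks of 123 bp overlapped an antibody 1 peak, 30.7% of the 4014 peaks of 300 to 499 bp, 90.2% (87.6% to 92.4%) of the 640 peaks of 500 to 999 bp, and 50 of the 51 peaks of 1000 bp or wider.

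**Figure D1:**
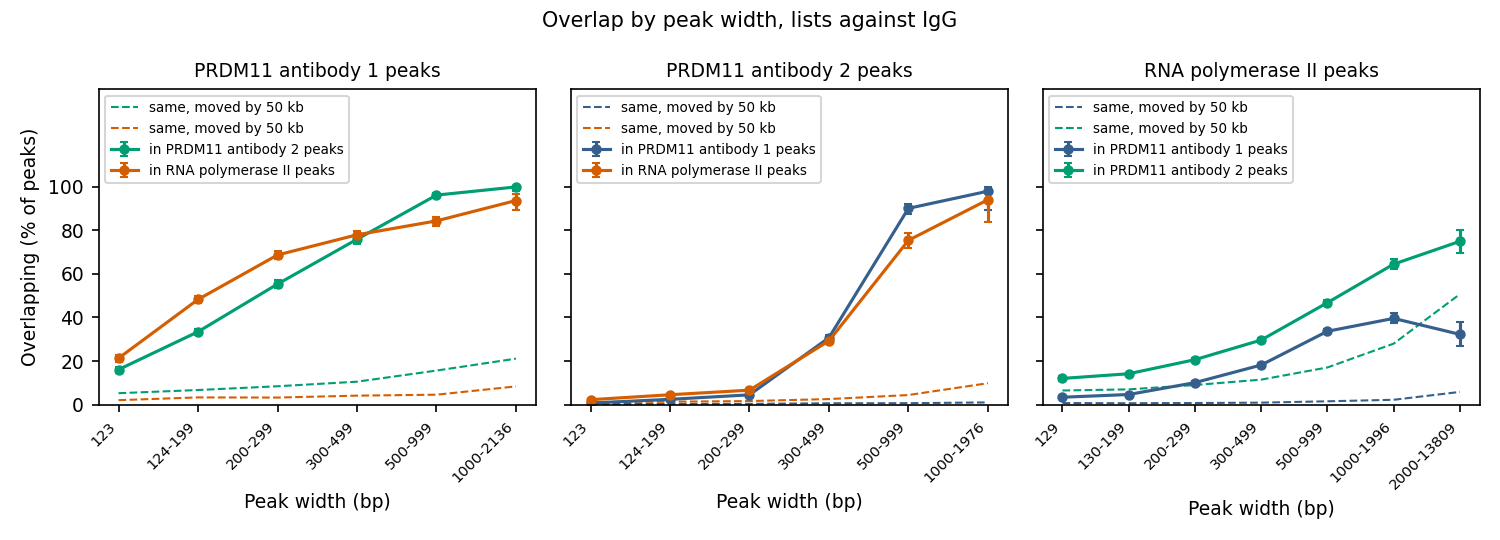
Share of peaks (percent, vertical axis) that overlap a peak of another library by at least 1 bp, by peak width in bp (horizontal axis), for the lists called against IgG; points are observed shares with exact 95% binomial intervals, and dashed lines are the same lists after a move of 50 kb. Shares of antibody 1 peaks in antibody 2 peaks rise from 16.1% at 123 bp to 96.2% at 500 to 999 bp.

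The 10 widest shared regions were taken as examples, by width because the lists carry no score. The widest antibody 1 peak lay on chromosome 18 at 61033139 to 61035274 (2136 bp). It coincided with the widest antibody 2 peak (61033303 to 61035278, 1976 bp) and held an RNA polymerase II peak at 61034105 to 61034998. The next lay on chromosome 8 at 128749175 to 128751282 (2108 bp), with an antibody 2 peak of 784 bp at its left end and no RNA polymerase II peak. Further wide regions on chromosome 11 (10878831 to 10880843, 2013 bp) and chromosome 15 (76628843 to 76630787, 1945 bp) overlapped antibody 2 peaks of 1665 bp and 1491 bp and RNA polymerase II peaks of 1093 bp and 1056 bp. The region on chromosome 6 (86302579 to 86304445) overlapped a 1422 bp RNA polymerase II peak, and that on chromosome 13 (92050670 to 92052535) one of 266 bp. The remaining regions lay on chromosome 11 (118270942 to 118272780), chromosome 22 (24199022 to 24200824), chromosome 17 (18086677 to 18088427) and chromosome 12 (42876539 to 42878288). The chromosome 12 region, like that on chromosome 8, held no RNA polymerase II peak. In each of the 10, peaks of both antibodies were also present in the lists called against input. However, 2 of the 10 regions, on chromosomes 18 and 13, lay in blocks of closely spaced input-list peaks (described below). The chromosome 18 block had 897.4 antibody 1 and 1015 antibody 2 peaks per Mb against input, so presence against input says little there. The chromosome 13 block was sparser, with 52.5 and 235 per Mb.

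Comparison with RNA polymerase II asks how far PRDM11 antibody peaks coincide with its called peaks, which need not cover every transcribed site. Antibody 1 peaks did so in 7446 of 13499 cases, or 55.2% (54.3% to 56.0%), against 1.23% for shuffled peaks and 3.32% after a move of 50 kb, a 16.6-fold difference from the latter. Antibody 2 peaks did so in 14886 of 465837 cases, or 3.20% (3.15% to 3.25%), against 0.896% for shuffled peaks and 1.23% after the move, a 2.60-fold difference. The 50161 RNA polymerase II peaks limit the share that the far longer antibody 2 list can reach, so the shares of the 2 antibodies are not directly comparable. The coincidence of antibody 1 with RNA polymerase II was local: moving antibody 1 peaks by 300 bp lowered the share to 44.6%, 1000 bp to 17.7% and 2000 bp to 6.58%. At 10000 bp the share was 4.44%, still above the 3.32% at 50 kb. Another 1451 antibody 1 peaks (10.7%) lay within 1000 bp of an RNA polymerase II peak without touching it, and 2295 (17.0%) lay more than 50 kb away. In the lists called against input, 44.9% of antibody 1 peaks and 6.29% of antibody 2 peaks overlapped RNA polymerase II peaks, 2.00 and 1.72 times their shares after the move.

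**Figure D2:**
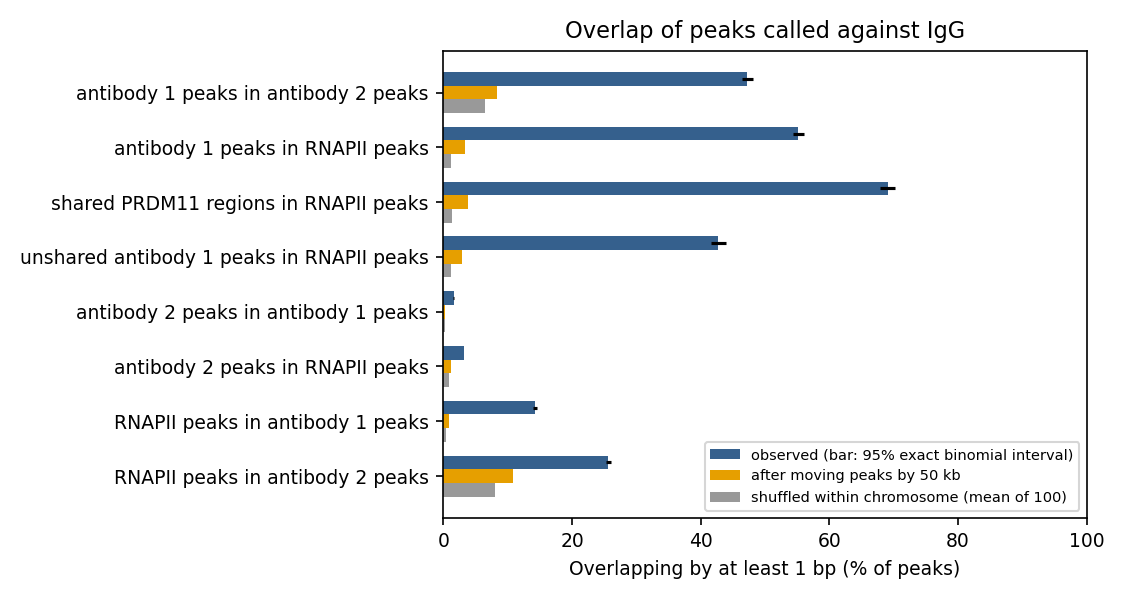
Share of peaks (percent, horizontal axis) in each list that overlap another list by at least 1 bp, all called against IgG; blue bars are observed shares with exact 95% binomial intervals, orange bars the shares after a move of 50 kb and grey bars the mean of 100 shuffles within chromosomes. Antibody 1 peaks overlap RNA polymerase II (RNAPII) peaks at 55.2% and antibody 2 peaks at 47.2%, both above the orange and grey bars.

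Taking both comparisons together, antibody 1 peaks fell into 4 classes. Those in both antibody 2 and RNA polymerase II peaks numbered 4403 (32.6%) and had a median width of 321 bp. A further 1972 (14.6%, median 204 bp) were in antibody 2 peaks only, 3043 (22.5%, median 181 bp) in RNA polymerase II peaks only, and 4081 (30.2%, median 128 bp) in neither. Shared PRDM11 regions overlapped RNA polymerase II in 69.1% of cases (67.9% to 70.2%) and unshared antibody 1 peaks in 42.7% (41.6% to 43.9%). This difference was not present at every width. Among 123 bp peaks, 37.8% of shared and 18.1% of unshared peaks overlapped RNA polymerase II, and among peaks of 124 to 199 bp 56.6% and 44.1%. Among peaks of 200 to 299 bp the shares were 68.1% (65.6% to 70.5%) and 69.5% (66.8% to 72.2%), and among those of 300 to 499 bp 76.9% (74.7% to 79.0%) and 81.4% (77.6% to 84.8%). Among peaks of 500 to 999 bp the shares were 84.2% of 1202 shared and 89.4% (76.9% to 96.5%) of 47 unshared peaks. In these wider classes the unshared share was thus the higher one. The intervals overlapped, which does not show that the shares are equal. No peak of 1000 bp or wider was unshared.

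**Figure D3:**
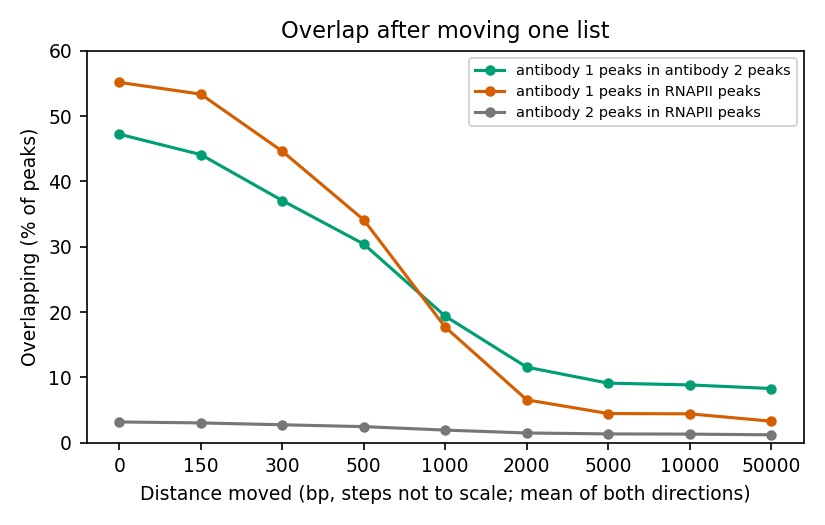
Share of peaks (percent, vertical axis) that still overlap the other list after all peaks of the first list are moved along the chromosome by the distance on the horizontal axis (bp, steps not to scale, mean of both directions), lists called against IgG. The share of antibody 1 peaks in RNA polymerase II (RNAPII) peaks falls from 55.2% unmoved to 6.58% at 2000 bp.

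Seen from RNA polymerase II, 14.3% (14.0% to 14.6%) of its 50161 peaks held an antibody 1 peak and 25.6% (25.3% to 26.0%) an antibody 2 peak, against 0.902% and 10.8% after a move of 50 kb. RNA polymerase II peaks with both antibodies (4845) had a median width of 506 bp, and those with neither (34987) of 215 bp. The share with an antibody 1 peak was 3.36% at the minimum width of 129 bp and 39.6% (37.3% to 41.9%) among 1806 peaks of 1000 to 1996 bp. Among the 276 peaks of 2000 bp or wider it was lower, at 32.2% (26.8% to 38.1%), though this interval overlapped that of the class before it. The share was 18.1 times that after the move among peaks of 1000 to 1996 bp and 5.56 times in the widest class. Of the 5 widest RNA polymerase II peaks, 3 held no antibody 1 peak: the widest, on chromosome 14 at 106317108 to 106330916 (13809 bp), and the next, on chromosome 17 at 74265116 to 74275174 (10059 bp), had 9 antibody 2 peaks each. The domain on chromosome 17 at 56401840 to 56411661 (9822 bp) held 1 antibody 1 peak and that on chromosome 11 at 65266313 to 65275606 (9294 bp) held 2. Another on chromosome 11, at 65189993 to 65199272 (9280 bp), held no antibody 1 peak and 2 antibody 2 peaks.

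The paired lists show how far calls for the same ChIP library depend on the control. Against input, antibody 1 had 54038 peaks, RNA polymerase II 80364 and antibody 2 486796. Of the peaks called against IgG, 81.3% for antibody 1, 89.4% for RNA polymerase II and 93.2% for antibody 2 were found again against input. Conversely, only 19.5% (19.1% to 19.8%) of antibody 1 peaks called against input were found against IgG, with 52.4% for RNA polymerase II and 89.1% for antibody 2. The additional peaks were concentrated on few chromosomes: chromosome 18 held 13630 antibody 1 peaks against input (25.2% of the list) and 328 against IgG (2.43%), and chromosome 3 held 11539 (21.4%) and 858 (6.36%). For RNA polymerase II, chromosome 18 held 11218 peaks against input (14.0%) and 1230 against IgG (2.45%).

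Within these chromosomes the additional peaks formed blocks of closely spaced peaks. Bins of 1 Mb with at least 50 antibody 1 peaks against input, and at least 5 times the number against IgG plus 1, joined into 22 blocks that spanned 93 Mb on 9 chromosomes. They held 50.2% of the antibody 1 peaks called against input and 4.17% of those called against IgG. On chromosome 18 the block from 51000001 to 62000000 had 897.4 antibody 1 peaks per Mb against input and 9.09 against IgG, 1015 and 84.8 antibody 2 peaks per Mb, and 800.4 and 50.9 RNA polymerase II peaks per Mb. On chromosome 3 the block from 86000001 to 91000000 had 970.6 antibody 1 peaks per Mb against input and 1.80 against IgG. Further blocks with over 300 antibody 1 peaks per Mb against input lay on chromosome 18 (22000001 to 27000000), chromosome 3 (147000001 to 154000000), chromosome 11 (119000001 to 123000000) and chromosome 1 (149000001 to 151000000). Outside the blocks, 31.6% of antibody 1 peaks called against input overlapped antibody 2 and 38.0% overlapped RNA polymerase II, which was 4.10 and 11.2 times their shares after a move of 50 kb. Leaving out the blocks changed the shares in the lists called against IgG little, to 47.3% and 55.1%.

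**Figure D4:**
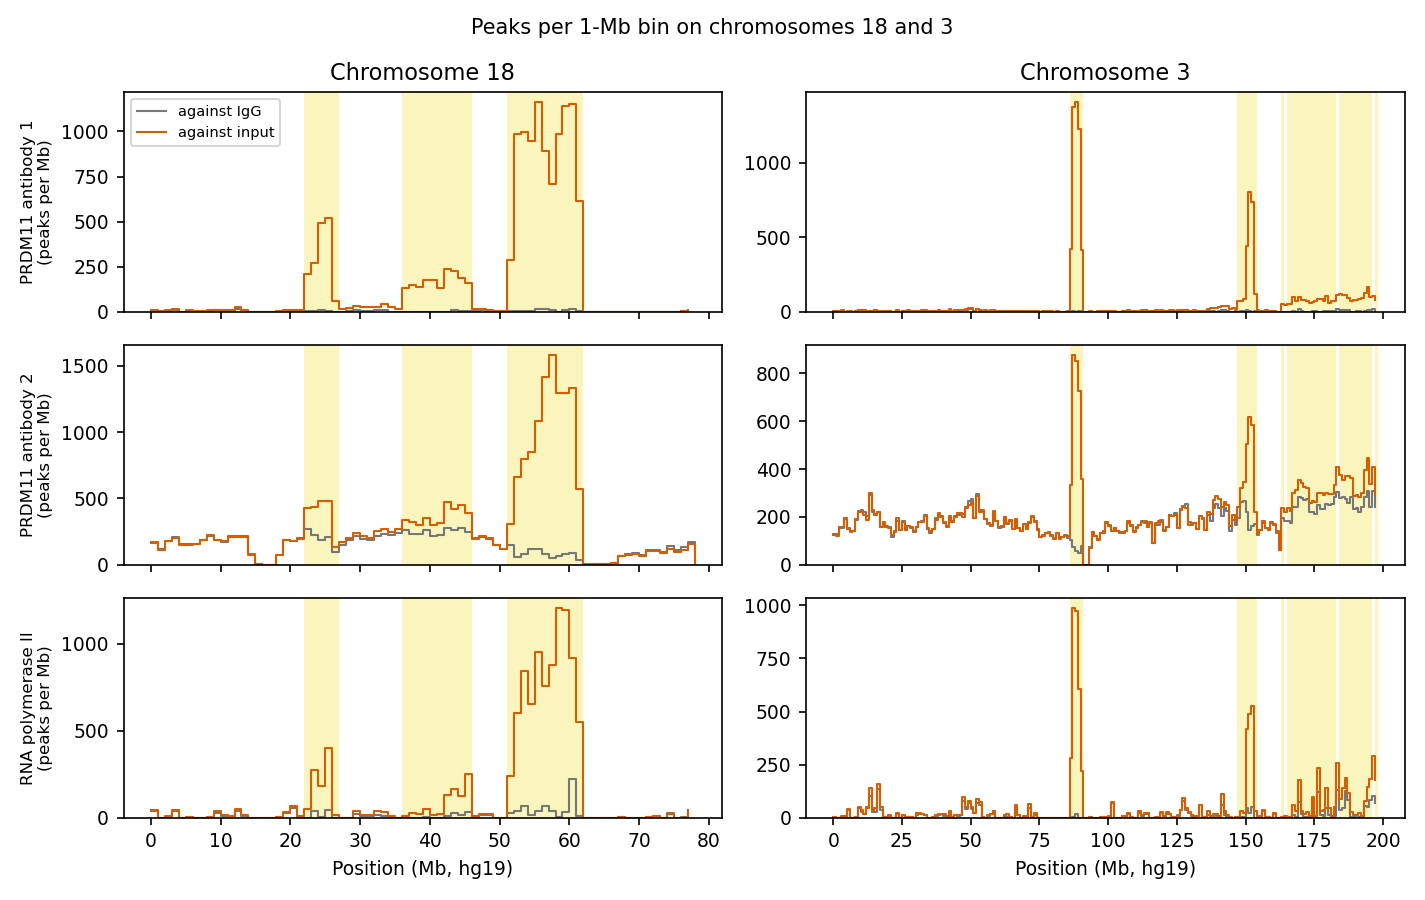
Number of peaks per 1-Mb bin (vertical axis, a separate scale in each panel) along chromosomes 18 and 3 (position in Mb, build hg19) for the 3 ChIP libraries, called against IgG (grey) and against input (orange); yellow marks the blocks defined from antibody 1. Inside the block at 51 to 62 Mb of chromosome 18 the orange line lies above the grey line in all 3 libraries, with averages of 897.4 against 9.09 peaks per Mb for antibody 1, 1015 against 84.8 for antibody 2 and 800.4 against 50.9 for RNA polymerase II.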

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

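Alternatives on width, blocks and empty stretches were chosen after seeing the data. Values below lie outside the exact interval of the reported share, beyond a factor of 1.5 for counts, or beyond 1 SD of the shuffles for chance overlap. In the lists called against input, the shares of antibody 1 in antibody 2, of antibody 1 in RNA polymerase II and of antibody 2 in RNA polymerase II were 34.8%, 44.9% and 6.29%, with 18799 shared regions; outside the blocks they were 31.6%, 38.0% and 3.91%, and 64.4% of shared regions overlapped RNA polymerase II. The number of shared regions against input outside the blocks was 8502, which lay within the factor of 1.5. Requiring at least 50% of the peak to be covered gave 30.5%, 48.9% and 2.56%, with 4117 shared regions, of which 59.8% were so covered by RNA polymerase II. Stricter coverage lowers the first 3 shares and the count by construction; the cause of the other differences was not tested. With both lists compared limited to peaks of 200 bp or more, the shares were 44.95%, 70.8% and 8.96%, with 2733 shared regions, of which 73.2% overlapped RNA polymerase II; over the 50-kb move the first 3 shares were 31.1, 23.8 and 6.77 times as high, against 5.68, 16.6 and 2.60 with all widths. With antibody 1 against IgG and the other list against input, antibody 1 overlapped antibody 2 at 48.2% and RNA polymerase II at 57.8%. Limiting the IgG lists to chromosomes 1 to 22 and X, or to positions outside the blocks, left the 4 shares within their intervals, and 5751 shared regions were found against both controls. Moving peaks by 50 kb gave chance overlaps of 8.31%, 3.32% and 1.23% in place of 6.47%, 1.23% and 0.896%, and shuffling outside empty stretches gave 6.86% for antibody 1 in antibody 2 and 0.948% for antibody 2 in RNA polymerase II. A stricter threshold and lists of equal length were not run because the lists carry no score, nor were other promoter windows, for lack of a gene annotation of build hg19 here. Read depth is unknown, so how many 123 bp peaks rest on few reads is open.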

Other observations

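The tests in this part were chosen after their results were seen, except that of antibody 1 peaks at least 5 kb from RNA polymerase II, which was added after the other overlaps were known but before its own result was; the lists with different controls were planned, but not their ratio to the move as a test. Inside RNA polymerase II peaks, antibody 1 peaks lay towards the middle. Of 3711 antibody 1 midpoints inside RNA polymerase II peaks of 500 bp or wider, 61.8% (60.2% to 63.3%) fell in the central 50% of the peak, where even placement gives 50%. For antibody 2 the share was 53.5% (52.3% to 54.8%) of 6015 midpoints. In RNA polymerase II domains of 2000 bp or wider, 44.7% (36.9% to 52.7%) of 161 antibody 1 midpoints were central, an interval that includes even placement.

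A stretch of chromosome 18 from 62000001 to 67000000, directly next to the block that ends at 62000000, was almost empty in all 6 lists. It held 35 antibody 2 peaks in each of the 2 antibody 2 lists over 5 Mb, where the median 1-Mb bin of the genome held 161 in the list called against IgG, and 0 antibody 1 or RNA polymerase II peaks against either control. It was 1 of 9 runs of at least 3 Mb in which every 1-Mb bin held under 10% of that median in both antibody 2 lists. The others lay on chromosomes 1, 6, 7, 9, 12, 16, 18 (15000001 to 18000000) and 21. Assembly gaps were not marked here, so runs that hold gaps were not told apart from runs that do not.

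The overlap of the 2 PRDM11 antibodies was tested against 3 explanations. The first was that both antibodies picked up sites with a called RNA polymerase II peak and nothing else. Antibody 1 peaks at least 5 kb from any such site should then overlap antibody 2 no more than after a move of 50 kb. Of these 4019 antibody 1 peaks 26.8% (25.4% to 28.2%) overlapped, 4.24 times the share after the move, which argues against it as the whole account. Transcribed sites without a called peak, in 1 RNA polymerase II library of unknown depth, would escape this test. It therefore cannot decide about transcribed sites in general. Chance overlap of wide peaks, as the whole account, was argued against by the 3.08-fold ratio among 123 bp antibody 1 peaks. That ratio says nothing about wide peaks themselves, of which 96.2% overlapped at 500 to 999 bp, against 15.6% after the move. The shared IgG control was argued against by the 5.45-fold ratio with different controls. Recognition of PRDM11 by both antibodies stays a hypothesis, because sites that precipitate with many antibodies could give such overlap where calling against IgG, which would reduce them, left some, and no library without PRDM11 was analysed here.

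The 365239 antibody 2 peaks of 123 bp raise the question of background. Calls placed without regard to other peaks would meet RNA polymerase II peaks as often as after a move of 50 kb, but the ratio was 1.92 (2.22% against 1.15%), so such calls may account for many of these peaks but not for all. Background calls that gather near RNA polymerase II peaks, or that stem from the shared IgG control, would escape this test. How many of the 123 bp peaks are background stays open. A further test, of whether most of these peaks are background, used their excess over the move (1.07 percentage points) and was dropped after its value was seen: the antibody 1 and RNA polymerase II lists are too short to overlap more than a small part of them, which fixes its outcome.

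For the blocks of closely spaced peaks in the input lists, binding by PRDM11 alone was taken to leave RNA polymerase II at even density. RNA polymerase II peaks against input were 10.8 times as dense inside the blocks as outside. With looser and stricter limits for a block the values were 7.23 and 17.2. The 2 densest blocks held 8804 and 3065 of the 20584 such peaks inside blocks. The block on chromosome 3 at 163000001 to 164000000 lay below the outside density (5.0 against 20.55 per Mb), and the other blocks above it. Antibody 1 and RNA polymerase II peaks often coincide in the IgG lists, so PRDM11 binding could itself vary with RNA polymerase II density. The density of RNA polymerase II therefore cannot decide. Both lists of a library come from the same ChIP library, so binding alone would raise peaks against either control. Inside the blocks antibody 1 was 31.5 times as dense as outside against input and 1.36 times against IgG, which the block rule partly fixes. For RNA polymerase II, not used to define the blocks, the values were 10.8 and 1.89. These values argue against binding alone as the whole account of the additional input-list peaks. An input library with fewer reads in the blocks, relative to the ChIP and IgG libraries, than elsewhere would raise input-list peaks in every library, and the ratio of input-list to IgG-list peaks was 2.12 times as high inside as outside for antibody 2 and 5.70 times for RNA polymerase II, the libraries not used to define the blocks. These pooled values rest largely on the 2 densest blocks, where they go with that account. Without those blocks the ratios were 1.46 for antibody 2 and 3.03 for RNA polymerase II. Of all 22 blocks, 8 for antibody 2 and 2 for RNA polymerase II lay under 1.2. At or over 1.5 lay 8 for antibody 2 and 18 for RNA polymerase II. For the 20 blocks other than the 2 densest, as a set, the account stays open. Extra copies of these segments in the cells, present to a different extent in the input, are a candidate explanation that the lists cannot decide, since they hold no read depth. Peak density against IgG went both ways: over all 22 blocks it was 1.32 (antibody 2), 1.36 (antibody 1) and 1.89 (RNA polymerase II) times that outside; in the 2 densest blocks together antibody 2 was at 0.526 times, while antibody 1 and RNA polymerase II lay above the outside 4.45 and 16.3 per Mb on chromosome 18 (9.09 and 50.9) and below them on chromosome 3 (1.80 and 4.60).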
